A study of Mus musculus with 13 samples.

How the data were processed

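RNA of whole quadriceps lysates was measured in 13 libraries, in 4 groups: young vehicle of batch 1 (replicates 1, 3, 4 and 5), aged vehicle of batch 1 (replicates 2, 3 and 4), aged vehicle of batch 2 (replicates 2, 3 and 8) and aged SW033291 of batch 2 (replicates 1, 4 and 6). Groups, batches, ages and doses were taken from the labels. Per the submitters' processing notes, STAR, RSEM, DESeq2, DESeq and the genome build mm9 were used, with versions and the order of the steps not given in the sources used here.

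The authors deposited 1 table of TPM values with 24015 genes for the 13 libraries, and each library sums to the same total over the genes listed. TPM keep no record of the reads behind them, so depth and counting error are unknown, and read counts were not used here. The authors also deposited a table for aged against young vehicle with 813 genes and one for SW033291 against vehicle with 24013 genes. Per the file headers, both tables hold a log2 fold change with its standard error, also on the log2 scale. Per the file headers, both hold an unadjusted p-value, and the age table also an adjusted p-value. Per the file headers, the column of test statistics is a score per gene made by DESeq2, and the column of mean levels holds a mean of normalised counts, a signal over the libraries that the authors compared. The libraries and covariates that entered either table are not given in the sources used here. All genes of the authors' deposited age table had an adjusted p of at most 0.0999, so that table was taken as part of a longer one.

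The gene names of the deposited TPM table did not belong to the values beside them. As deposited, the mean TPM of a gene and its mean level in the authors' deposited table of SW033291 had a Spearman correlation of -0.0174 across 24011 genes, and the log2 differences of SW033291 against vehicle a Pearson correlation of -0.0075 across 6365 genes with a mean level of at least 50. The values were found to follow the alphabetical order of the names, capitals before lower case, while the names stood in another order. A total of 27 names that a spreadsheet had turned into dates were restored to gene symbols, and all names were sorted and put back on the values. The same correlations were then 0.960 and 0.847, the log2 changes of the authors' deposited age table had a correlation of 0.959 across 813 genes, and 99.9% of those genes had the same direction. Genes are not independent replicates, and these correlations describe only whether the names fit. Moving the sorted names by 1 place up or down gave correlations of 0.0437 and 0.0449 for the log2 differences of SW033291. One of these genes, Mir6236, differed by over 1 log2 unit from the authors' deposited table of SW033291, and without it the lowest correlation of these log2 differences in 50 blocks along the sorted table was 0.926. Every gene value rests on this restored order. In the authors' deposited table of SW033291, 115 of the 11858 tested genes it lists had a mean level of 0, among them Hba-a1, Hbb-bs, Gm14305, Gm7367, Eif3j1 and Mir6340, so values of these genes rest on the TPM table alone.

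Values were analysed as log2(TPM + 1) with limma 3.58.1 in R 4.3.3, for 11876 genes at 1 TPM or more in at least 3 libraries. On this scale the change of a gene near or below 1 TPM is understated. One linear model with a coefficient per group was fitted to all 13 libraries, with moderated variances and a trend on expression, and p-values were adjusted by the Benjamini-Hochberg method in each comparison, with 0.05 as the threshold. The comparisons were aged vehicle against young vehicle within batch 1, SW033291 against vehicle in aged muscle within batch 2, and aged vehicle of batch 2 against batch 1. Batch is part of each group, and young and treated libraries each exist in 1 batch only. The tests, comparisons, gene lists and the rule for the genes named were fixed before the data were examined.

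Of 41 gene lists written from general knowledge, 37 with at least 5 tested genes were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, all from limma. A further 3 lists were too small, and 1 was set aside for a check of sample labels and not tested. The p-values of single genes were also adjusted over the genes of their list alone. That adjustment does not correct for the number of lists, so some such passes are due to chance. The genes called with age were tested as sets in the SW033291 comparison with fry, adjusted over both directions. Marker lists of cell types describe transcript levels in whole muscle, not numbers of cells. Lists of granulocyte, erythroid and B cell precursors and of dividing cells were written after neutrophil transcripts had been seen to differ between libraries. The levels of these lists as a whole had not been read then. Of their genes, 5 of 11, 2 of 12, 3 of 10 and 5 of 8 were also in the lists fixed beforehand. The levels of those genes may have been seen, so the choice was not blind for them.

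The genes named were, in each of the age and SW033291 comparisons, the 10 largest rises and 10 largest falls among genes that passed, had groups that did not overlap and reached a mean of 5 TPM. Where fewer than 5 passed in a direction, up to 5 genes with the smallest p were named as not passed. Up to 4 genes with the smallest p came from each list described. The genes Hpgd, Ptger2, Ptger4, Ptges, Fbxo32, Trim63, Mstn, Tgfb1, Ppargc1a, Tfam, Cdkn1a, Cdkn2a, Col1a1 and Col3a1 were always named. Genes called in opposite directions in both comparisons would also have been named, which was not possible because SW033291 had no calls. The precursor genes of the closing part, Slc15a2, Aldoart1 and the genes called only under an alternative were chosen after their values were seen.

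The model was tested on simulated data with the means and spreads of the real libraries, over 11876 genes. Of 100 genes changed by 1 log2 unit, 68% were called for age, 67% for SW033291 and 65% for the batches. Of 100 genes changed by 2 log2 units, 97%, 94% and 99% were called. False calls made up 4.62%, 6.40% and 2.96% of the calls. Genes were simulated independently of each other, with normal spread. Shared movement of genes and deviating libraries were not simulated, so these shares may not carry over to the real libraries.

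Alternatives recomputed the counts of genes with pseudocounts of 0.1 and 5, no filter, a filter at 5 TPM, median-of-ratios scaling, quantile normalization, rescaling without the 20 most abundant genes, robust and weighted fits, the compared groups alone, a replicate block, other thresholds, other aged vehicle libraries, and each library left out in turn, each for the comparisons that it applied to. Gene lists were not refitted with a pseudocount of 5, no filter, or robust or weighted fits. The genes called with age were followed in the SW033291 comparison only with a pseudocount of 0.1, a filter at 5 TPM, quantile normalization, other sets of age genes, the 3 libraries with granulocyte precursor transcripts left out and each library left out in turn. Chosen after the data were seen were the fits with aged vehicle of batch 2 in place of batch 1, with the 3 libraries holding granulocyte precursor transcripts left out, and with a trend on transcript length and GC content removed within each library, and for gene lists also median-of-ratios scaling, rescaling without the 20 most abundant genes and the aged vehicle libraries of both batches. Length and GC were taken from a reference annotation of another genome build by gene symbol, for 11789 of the tested genes (99.3%), and coordinates are not given for that reason. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.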

Results

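Polyadenylated RNA of whole quadriceps muscle was sequenced in 13 libraries from C57BL/6 mice. The libraries fell into 4 groups, and treatment lasted 4 weeks. Batch 1 held 4 libraries of young mice (3 months) and 3 libraries of aged mice (labelled as over 24 months), all given vehicle. Batch 2 held 3 libraries of aged mice given vehicle and 3 of aged mice given SW033291, an inhibitor of the prostaglandin-degrading enzyme 15-PGDH, at 5 mg/kg daily. Levels were given as TPM, a share of all transcripts in a library, which keeps no record of sequencing depth, so the depth of each library is unknown and no interval from counting is given. Between 10710 and 11687 genes stood at 1 TPM or more per library, and the 20 most abundant genes took 38.4% to 45.1% of all TPM. Pearson correlations of log2(TPM + 1) across genes, which are not independent replicates, lay between 0.946 and 0.991 for libraries of the same group. The lowest involved aged vehicle batch 1 replicate 4. The gene names of the TPM table did not match its values as deposited and were restored by their order before any comparison, with the checks given in the methods. Nothing in the labels states that each library came from a separate animal, so p-values measure the spread between these samples.

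The comparison of aged with young vehicle muscle in batch 1 asks which transcripts differ with age. Among the transcripts that rose were those of single genes of calcium handling, denervation and growth arrest, and among those that fell were transcripts of collagens and other matrix proteins. Sln, which encodes sarcolipin, an inhibitor of the sarcoplasmic reticulum calcium pump, rose from 4.70 ± 1.63 TPM (SD, n = 4) in young to 123 ± 56.7 TPM (SD, n = 3) in aged muscle. Cdkn1a, which encodes the cell cycle inhibitor p21, rose to 48.2 ± 17.4 TPM, 3.42-fold the young level on the log2(TPM + 1) scale. Gadd45a, a stress-induced gene that also responds to loss of innervation, rose from 53.5 to 158 TPM. Col1a1 and Col3a1, which encode chains of fibrillar collagens I and III, fell from 46.2 ± 4.57 to 9.93 ± 4.14 TPM and from 40.4 ± 11.8 to 9.85 ± 4.11 TPM.

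With limma and Benjamini-Hochberg adjustment over 11876 genes, 54 genes passed an adjusted p of 0.05 with age, 44 higher and 10 lower. At an unadjusted p under 0.05 the count was 1178, against 593.8 expected by chance. The median log2 difference of all genes was 0.06. All 54 genes had young and aged libraries that did not overlap. Among all genes tested 1372 (11.6%) had groups that did not overlap, where chance gives 5.71%. The balance of directions depended on the scaling: median-of-ratios scaling gave 36 higher and 20 lower, quantile normalization 41 and 30, and leaving out the 20 most abundant genes 37 and 28. The count also depended on single libraries. It was 19 without young replicate 1, 26 without young replicate 4, 21 without young replicate 5, 19 without aged batch 1 replicate 2 and 92 without aged batch 1 replicate 4. Of those 92 genes, 40 were among the 54.

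Sln had a log2 change of 4.40 (SE 0.43, limma adjusted p = 5.4e-04). Other large rises were in genes of secreted factors, signalling and the sarcomere. Ostn, which encodes the muscle-secreted peptide osteocrin, rose by 2.38 on the log2 scale (SE 0.38), and Ankrd1, a stress-induced ankyrin repeat protein of the sarcomere, by 2.14 (SE 0.41). Rrad, a small GTPase that restrains calcium channels, rose by 2.87 (SE 0.54), and Eda2r, a receptor of the tumour necrosis factor family, by 1.82 (SE 0.26). Cpne2, a calcium-dependent membrane-binding protein, rose by 2.33, Ttc9, a tetratricopeptide repeat protein, by 2.00, and Aif1l, an actin-binding protein, by 1.97. Krt18, a keratin, was listed at 0 in all 4 young libraries and at 3.86, 7.45 and 3.83 TPM in aged replicates 2, 3 and 4. Cdkn1a rose by 1.77 (SE 0.26), Gadd45a by 1.44 beyond the median of all genes (SE 0.22), and Gdf11, a ligand of the TGF-beta family, by 1.60 (SE 0.28). The limma adjusted p of the genes named here lay between 5.4e-04 and 0.039.

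The largest falls included genes of the extracellular matrix. Sfrp2, a secreted modulator of Wnt signalling, fell by 2.23 on the log2 scale (SE 0.33), Col1a1 by 2.17 (SE 0.36), Col3a1 by 1.96 (SE 0.36) and Col1a2 by 1.93 (SE 0.30). Thbs4, a matrix glycoprotein of tendon and muscle, fell by 1.61, Sparc, a collagen-binding glycoprotein, by 0.96, and Serpinf1, a secreted serpin, by 1.23. Outside the matrix, Nrep, a regulator of cell motility, fell by 1.66, Exoc7, an exocyst subunit, by 0.77, and Slc37a4, the glucose-6-phosphate transporter of the endoplasmic reticulum, by 0.55. The limma adjusted p of these 10 genes lay between 0.0079 and 0.033. Of 24 named calls, 8 held in each of the 7 fits that left out 1 library: Sln, Cpne2, Ttc9, Eda2r, Gadd45a, Cdkn1a, Serpinf1 and Exoc7. The other 16 kept their direction but ended in at least 1 such fit, with limma adjusted p up to 0.15. Col1a1 ended without young replicate 1, without young replicate 5 and without aged replicate 2, where its adjusted p was highest (0.081). Col1a2 (0.069) and Sfrp2 (0.058) ended without aged replicate 2 and Ostn (0.050) without young replicate 5. The calls of Rrad, Aif1l and the ribosomal protein gene Rplp0 ended whichever of the 7 libraries was left out.

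**Figure D1:**
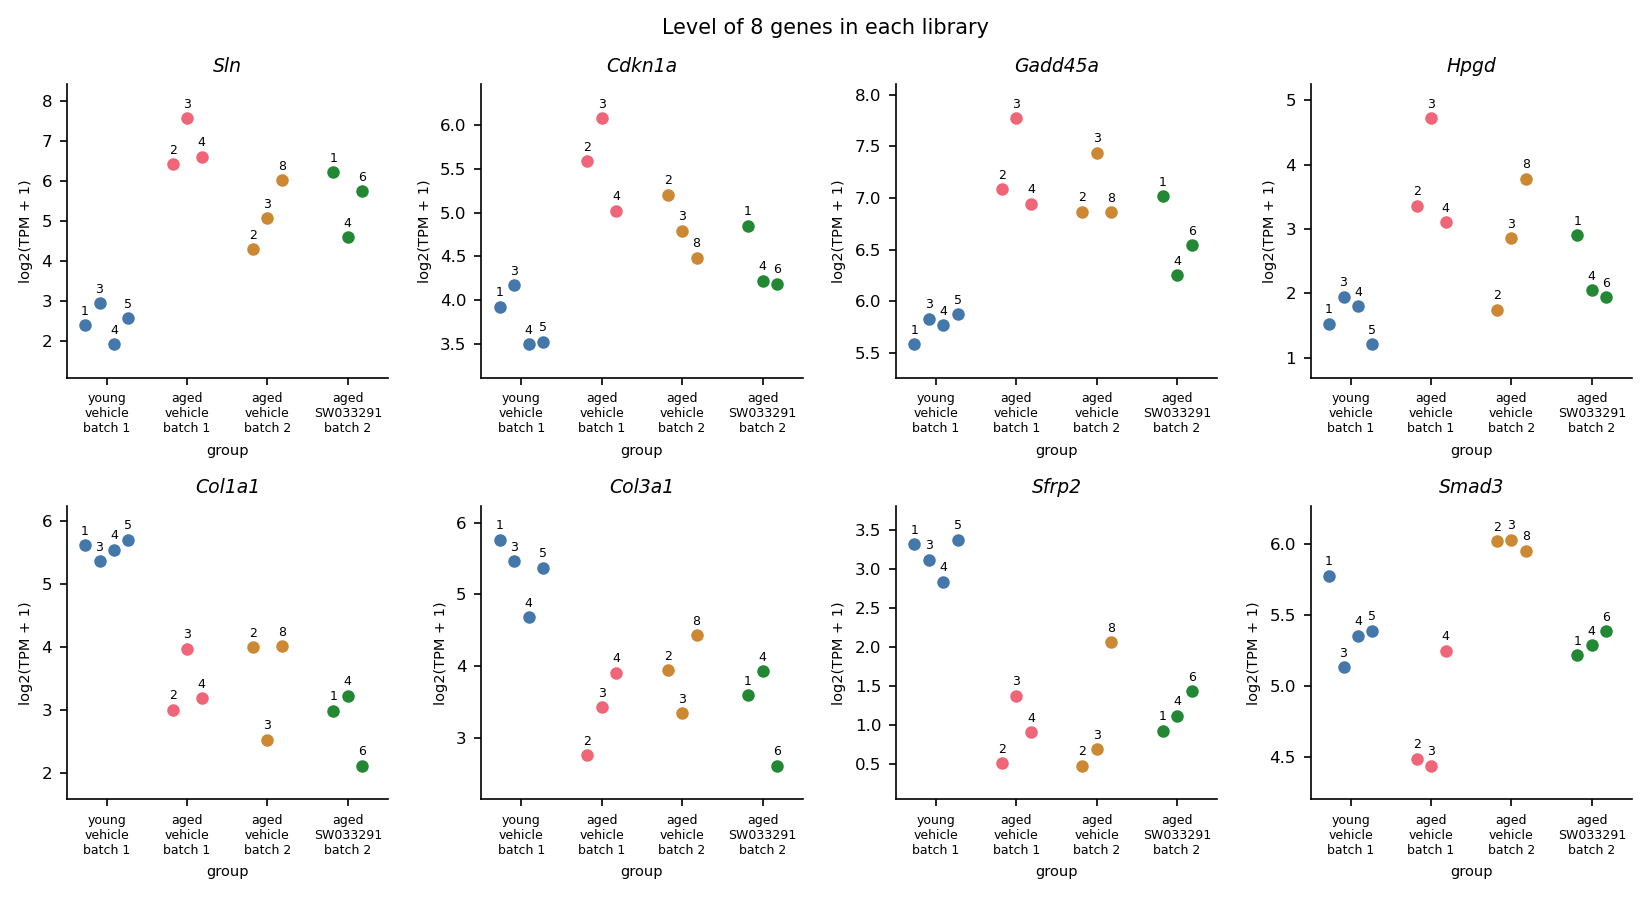
Level of 8 genes in each library, as log2(TPM + 1) on the vertical axis, by group on the horizontal axis; each point is 1 library with its replicate number. Sln, Cdkn1a and Gadd45a stood above all 4 young libraries in the 3 aged libraries of batch 1, and Col1a1, Col3a1 and Sfrp2 stood below them.

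Hpgd encodes 15-PGDH itself, the target of SW033291. Its mean was 2.14 ± 0.68 TPM in young and 14.1 ± 9.81 TPM in aged muscle of batch 1, and all 3 aged libraries lay above all 4 young ones. The difference of 2.10 on the log2 scale (SE 0.45) did not pass over all genes (limma adjusted p = 0.060). Hpgd passed when adjusted over the list alone, among 17 tested genes of prostaglandin synthesis, degradation and reception (limma adjusted p = 0.0069). It passed over all genes without aged batch 1 replicate 4 (limma adjusted p = 0.047). The aged vehicle libraries of batch 2 stood at 2.36, 6.23 and 12.8 TPM of Hpgd. Of the receptors of prostaglandin E2, Ptger4 differed by -0.26 (limma adjusted p = 0.86), and Ptger2 was not tested, since it reached at most 0.29 TPM. Ptges, a synthase of prostaglandin E2, differed by -0.48 (limma adjusted p = 0.62).

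Cdkn2a, which encodes the senescence marker p16, differed with age by 1.81 (SE 0.43) without passing (limma adjusted p = 0.077), except without aged replicate 3 (limma adjusted p = 0.047). The ubiquitin ligases of muscle atrophy, Fbxo32 and Trim63, differed by 0.73 (limma adjusted p = 0.19) and 0.64 (limma adjusted p = 0.24). Mstn, which encodes the growth inhibitor myostatin, differed by -0.42 (limma adjusted p = 0.56). Tgfb1, which encodes the cytokine TGF-beta 1, differed by 0.01 (limma adjusted p = 1.00). The mitochondrial regulators Ppargc1a and Tfam differed by 0.10 and 0.14 (limma adjusted p = 0.95 and 0.82).

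Among 37 gene lists fixed before the data were examined, limma's camera with a preset correlation of 0.01 called 17 with age, 6 higher and 11 lower. With an estimated correlation between genes 0 of the 17 calls held, and fry, which tests each list on its own genes, called 6. The fibrillar and basement membrane matrix list, the scaffold around muscle fibres, had the lowest p of the lower lists. Its median change minus that of all genes was -0.66, 38 of 42 genes were lower, and the camera adjusted p was 6.8e-25 (adjusted p = 0.18 with an estimated correlation). Of its genes 4 passed over all genes and 16 when adjusted over the list alone. Tenocyte markers, genes of tendon cells that include Thbs4 and Fmod, had a median of -0.95 (camera adjusted p = 5.1e-07, and adjusted p = 0.18 with an estimated correlation). Markers of fibro-adipogenic progenitors, the matrix-producing cells between fibres, had -0.59 (camera adjusted p = 1.4e-10, and adjusted p = 0.22 with an estimated correlation), with Fbln1 and Pi16 among them. Complement genes had -0.58 (camera adjusted p = 4.1e-06, and adjusted p = 0.40 with an estimated correlation). Of the tenocyte list 1 gene passed over all genes and 4 when adjusted over the list alone, of the progenitor list 0 and 3, and of the complement list 0 and 0. Fry called the tenocyte list (adjusted p = 0.049) and did not call the matrix list (adjusted p = 0.065).

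Genes that respond to denervation or encode the neuromuscular junction were higher with age as a list. Their median minus that of all genes was 0.29, 23 of 27 genes were higher, and the camera adjusted p was 8.8e-06 (adjusted p = 0.22 with an estimated correlation). Gadd45a passed over all genes, and 7 passed when adjusted over the list alone. Chrnb1, the beta subunit of the muscle acetylcholine receptor, had a log2 difference of 0.93, Runx1, a transcription factor induced in denervated muscle, 1.04, and Musk, the receptor kinase that organises the synapse, 1.38. The list of atrophy-associated ubiquitin ligases and FoxO targets was also higher (median 0.15, camera adjusted p = 0.013, and adjusted p = 0.40 with an estimated correlation). Its call ended without aged batch 1 replicate 2 (camera adjusted p = 0.12). Its genes Gadd45a and Cdkn1a passed over all genes, and 5 genes when adjusted over the list alone. Proteasome subunits, among them Psma7 and Psmb1, had a small median of 0.06 (camera adjusted p = 8.3e-04, and adjusted p = 0.39 with an estimated correlation). Their call ended under all 3 scalings tried (camera adjusted p = 0.053, 0.086 and 0.085). Autophagy and lysosome genes had 0.11 (camera adjusted p = 0.021, and adjusted p = 0.34 with an estimated correlation), a call that also ended under the 3 scalings. Of the autophagy list 0 genes passed over all genes and 2 when adjusted over the list alone. Without young replicate 1, aged replicate 2 or aged replicate 3 of batch 1, the autophagy list had camera adjusted p of 0.054, 0.13 and 0.079.

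All 79 tested genes of cytosolic ribosomal proteins, the protein part of the ribosome, had positive log2 differences with age in batch 1. The list's median minus that of all genes was 0.21 (camera adjusted p = 2.3e-27, and adjusted p = 0.24 with an estimated correlation). Only Rplp0 passed over all genes, while 44 genes passed when adjusted over the list alone. As a difference from the mean of all libraries, the list's median was 0.13, 0.07 and 0.41 in aged replicates 2, 3 and 4. The highest young library stood at -0.02. Aged replicate 4 also held the most neutrophil transcripts. With the aged vehicle libraries of batch 2 in place of those of batch 1, the direction flipped to -0.16 (camera adjusted p = 0.011). Age and batch cannot be told apart in that fit, since all young libraries are of batch 1. Reads of ribosomal protein genes can be shared with pseudogenes, so their single values are uncertain.

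Contractile and metabolic genes of fast fibres were slightly lower with age in batch 1. Glycolysis and glycogen genes, among them Pygm, the muscle glycogen phosphorylase, and Ldha, lactate dehydrogenase, had a median of -0.28 (camera adjusted p = 3.2e-07, and adjusted p = 0.18 with an estimated correlation). Of these, 3 lower genes and 1 higher passed when adjusted over the list alone. The fall was largest in aged replicate 4, where the list's median against the young mean was -0.36. It was -0.09 and -0.10 in aged replicates 2 and 3, close to the lowest young library (-0.09, replicate 4). Fast fibre genes, among them Casq1, the calcium store protein, had -0.19 (camera adjusted p = 6.7e-05, and adjusted p = 0.11 with an estimated correlation). Of the fast fibre genes 0 passed over all genes and 2 when adjusted over the list alone. The fast fibre call ended under quantile normalization (camera adjusted p = 0.34). Myh4, the myosin heavy chain of the fastest fibres, differed by -0.45 without passing. It differed by 0.76 with the aged libraries of batch 2 in place of batch 1, where age and batch cannot be told apart.

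Several lists of other cell types were lower with age, with calls that depended on single libraries. Adipocyte markers had a median of -0.59 (camera adjusted p = 1.1e-04, and adjusted p = 0.56 with an estimated correlation), endothelial markers -0.30 (camera adjusted p = 5.3e-05, and adjusted p = 0.43 with an estimated correlation), and smooth muscle and pericyte markers -0.33 (camera adjusted p = 0.011, and adjusted p = 0.52 with an estimated correlation). Without aged batch 1 replicate 4 these calls ended, at medians of -0.44, -0.12 and -0.04 (camera adjusted p = 0.062, 0.26 and 0.71). In the fits that left out 1 library the adipocyte median was nearest to 0 without young replicate 1 (-0.20) and farthest from 0 without young replicate 4. As a difference from the mean of all libraries, the adipocyte list stood at 1.68, 1.23, -0.90 and -0.46 in young replicates 1, 3, 4 and 5. It stood at -0.53, 0.40 and -0.36 in aged replicates 2, 3 and 4. Only young replicates 1 and 3 thus lay above the aged libraries, and the fall with age rests on them. The smooth muscle call also ended without young replicate 3 (0.061) and without aged replicate 2 (0.058). Macrophage markers had -0.14 (camera adjusted p = 0.050, and adjusted p = 0.81 with an estimated correlation) and IGF and insulin signalling genes -0.08 (camera adjusted p = 0.035, and adjusted p = 0.43 with an estimated correlation). Both of these calls ended under several alternatives. The macrophage median was 0.02 without aged replicate 3, and its call also ended without young replicate 1, young replicate 3 or aged replicate 2 (camera adjusted p = 0.33, 0.32 and 0.089). The IGF call ended without young replicate 1, young replicate 3, aged replicate 2 or aged replicate 4 (camera adjusted p = 0.064, 0.061, 0.12 and 0.075).

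Neutrophil and red cell transcripts were far higher in some aged libraries than in others. S100a9, an abundant neutrophil protein, was listed at 0 in all 4 young libraries and stood at 0, 1.72 and 736 TPM in aged replicates 2, 3 and 4 of batch 1. The neutrophil list was called higher with age (camera adjusted p = 0.014, and adjusted p = 0.65 with an estimated correlation), but not without aged replicate 4 (camera adjusted p = 0.98). In batch 2, S100a9 stood at 290 TPM in aged vehicle replicate 2 and at 78.2 TPM in SW033291 replicate 4, and at 6.39 TPM or less in the other 4 libraries. The haemoglobin gene Hba-a1 passed with age, at 77.5, 115 and 899 TPM in aged replicates against 0, 0, 0 and 19.6 TPM in young ones. Near-identical globin copies can share reads, so its value is uncertain.

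**Figure D2:**
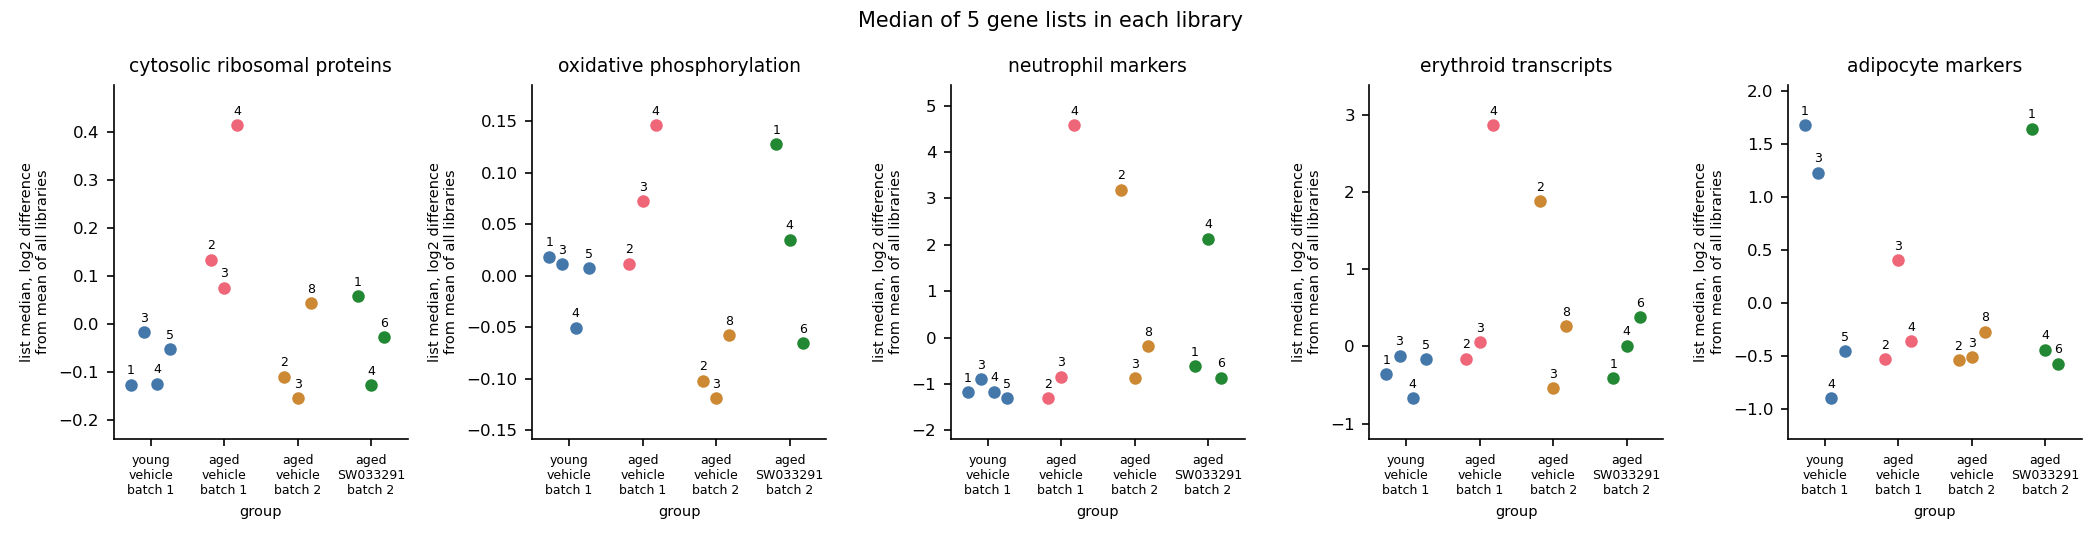
Median of 5 gene lists in each library, as log2 difference from the mean of all libraries on the vertical axis, by group on the horizontal axis; each point is 1 library with its replicate number. Neutrophil markers stood at 4.57, 3.19 and 2.13 in aged vehicle batch 1 replicate 4, aged vehicle batch 2 replicate 2 and SW033291 replicate 4, and adipocyte markers at 1.64 in SW033291 replicate 1.

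The authors' deposited table of age held 813 genes, 516 higher and 297 lower, of which 514 had an adjusted p under 0.05 there. Its log2 changes followed the TPM of the aged vehicle libraries of both batches pooled (r = 0.994 across 576 genes, which are not independent replicates) more closely than those of batch 1 alone (r = 0.977). Of the 54 genes called here, 49 were in the authors' deposited table, all 49 in the same direction and 46 at an adjusted p under 0.05. The authors' deposited table comes from the same series, and the restored gene names were checked against it. The shared directions are therefore no independent support. For Hpgd the authors' deposited table gave a log2 change of 2.22 with an adjusted p of 3.4e-04, and for Cdkn2a 2.54 with an adjusted p of 0.020. The authors' deposited table gave Cdkn1a a log2 change of 1.42 and Col1a1 one of -2.17.

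The comparison of SW033291 with vehicle in aged muscle of batch 2 asks what inhibition of 15-PGDH changes. No single gene passed. With camera's preset correlation, lists of oxidative phosphorylation, antigen presentation, adipocyte and ribosomal genes stood above the other genes, and none of these calls held with an estimated correlation. Genes of oxidative phosphorylation, the mitochondrial respiratory chain, were slightly higher relative to the other genes. TGF-beta pathway genes, among them Smad3, were lower without passing.

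With limma and Benjamini-Hochberg adjustment 0 of 11876 genes passed for SW033291, and the smallest adjusted p was 0.18. At an unadjusted p under 0.05 there were 1221 genes, 173 higher and 1048 lower, against 593.8 expected by chance. Most lay in the direction of the shift of all genes. The authors' deposited table of SW033291 held no such excess, with 2.74% of its DESeq2 p-values under 0.05. The median log2 difference of all genes was -0.13, and the shift depended on scaling, being near 0 under median-of-ratios scaling, -0.01 under quantile normalization and -0.10 without the 20 most abundant genes. The changes below are given minus the shift of -0.13 where they are called relative. Groups did not overlap for 2027 genes (17.1%), where chance gives 10%. Without SW033291 replicate 4, 1 gene passed in limma, the haemoglobin gene Hbb-bs (adjusted p = 0.035). It was listed at 0 in the 3 vehicle libraries and at 52.2, 0 and 156 TPM in SW033291 replicates 1, 4 and 6, and globin copies can share reads. The authors' deposited table of SW033291 held Hbb-bs and Hba-a1 at a mean level of 0.

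The genes with the smallest p that were higher, none of which passed, included a mitochondrial import factor and a transfer RNA enzyme. Inca1, an inhibitor of cyclin-dependent kinase, stood at 1.84 ± 0.21 TPM with vehicle and 4.75 ± 0.30 TPM with SW033291 (relative log2 difference 1.15, limma adjusted p = 0.18). Timm9, an import chaperone of the mitochondrial intermembrane space, stood at 29.2 ± 4.29 and 48.3 ± 3.29 TPM (relative difference 0.85, limma adjusted p = 0.18). Qtrt1, which modifies transfer RNA, had a relative difference of 1.22, and Pdzd11, a PDZ domain protein, 0.71 (limma adjusted p = 0.18 and 0.34). 1700020L24Rik was listed at 0 in the 3 vehicle libraries and at 2.19, 1.42 and 0.82 TPM with SW033291. It and Inca1 passed with a pseudocount of 0.1 (limma adjusted p = 0.014 and 0.044). The authors' deposited table of SW033291 gave these genes mean levels of 2.74 and 8.83 normalised counts. Their unadjusted DESeq2 p there was 0.21 and 0.24, so that table does not support these calls.

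Those that were lower, again without passing, included regulators of transcription and of signalling. Cxxc5, a zinc finger regulator of Wnt and BMP signalling, stood at 20.7 ± 7.44 TPM with vehicle and 8.59 ± 1.75 TPM with SW033291 (relative difference -1.01, limma adjusted p = 0.26). Stk40, a kinase-like protein, had a relative difference of -0.57 and Rgmb, a coreceptor of BMP, -0.65 (limma adjusted p = 0.26 for both). E130218I03Rik had -1.64 and Gm14305 -1.31 (limma adjusted p = 0.18 and 0.30), both at mean levels of 3.12 TPM or less. The authors' deposited table of SW033291 held a mean level of 0.168 normalised counts for the former and 0 for the latter, so it does not support these values.

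Hpgd stood at 7.12 ± 5.26 TPM with vehicle and 4.15 ± 2.02 TPM with SW033291, with overlapping groups (relative difference -0.37, limma adjusted p = 0.70). Mstn had a relative difference of -0.44 (limma adjusted p = 0.43), Cdkn2a 1.13 (limma adjusted p = 0.48) and Cdkn1a -0.27 (limma adjusted p = 0.61). The atrophy ligases Fbxo32 and Trim63 had relative differences of -0.05 and 0.08 (limma adjusted p = 0.78 and 0.95). Ppargc1a and Tfam, regulators of mitochondria, had 0.04 and -0.05 (limma adjusted p = 0.89 and 0.63). The prostaglandin genes Ptges and Ptger4 had 0.29 and 0.38 (limma adjusted p = 0.84 and 0.78). Tgfb1 had 0.30 (limma adjusted p = 0.87), Col1a1 -0.60 (limma adjusted p = 0.52) and Col3a1 -0.39 (limma adjusted p = 0.62).

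Camera called 7 of the 37 lists higher with SW033291 and 0 lower, with the preset correlation. The directions depended on the settings, with 8 higher and 2 lower under median-of-ratios scaling, 4 and 2 under quantile normalization, 6 and 1 without the 20 most abundant genes, and 7 and 2 with only the 2 groups compared. With an estimated correlation 0 of the 7 held, and fry called 0. The nuclear-encoded oxidative phosphorylation list had 68 of 78 genes higher, a median log2 difference of 0.12 and a median minus that of all genes of 0.25 (camera adjusted p = 1.6e-20, and adjusted p = 0.23 with an estimated correlation). Its genes with the smallest p were Ndufa3 and Ndufa12 of complex I, Cox7a1 of complex IV and Atp5e of the ATP synthase, at relative differences between 0.37 and 0.45. None of its genes passed, over all genes or when adjusted over the list alone. The aged vehicle libraries of batch 2 stood below all 4 young libraries in this list's median. SW033291 replicates 1 and 4 stood above all 3 of these vehicle libraries, and replicate 6 did not.

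Ribosomal protein genes had a relative median of 0.18 (camera adjusted p = 1.5e-07, and adjusted p = 0.96 with an estimated correlation), which fell to 0.04 once the trend on transcript length and GC content was removed (camera adjusted p = 0.98). Adipocyte markers, among them Fabp4, a fatty acid carrier, and Cfd, the adipokine adipsin, had 0.94 (camera adjusted p = 3.9e-07, and adjusted p = 0.96 with an estimated correlation). Without SW033291 replicate 1 the adipocyte median was 0.17 and the call ended (camera adjusted p = 0.067). Antigen presentation genes of MHC classes I and II had 0.25 (camera adjusted p = 0.0041, and adjusted p = 0.96 with an estimated correlation). Their call ended without aged vehicle replicate 3 (camera adjusted p = 0.67) and without SW033291 replicate 1 (0.33). Fast fibre genes had 0.20 (camera adjusted p = 0.0066, and adjusted p = 0.23 with an estimated correlation) and glycolysis genes 0.14 (camera adjusted p = 0.0091, and adjusted p = 0.96 with an estimated correlation). Both ended under quantile normalization and with the length and GC trend removed. The fast fibre call ended without SW033291 replicate 4 or 6 (camera adjusted p = 0.13 and 0.054), and the glycolysis call without aged vehicle replicate 2 or SW033291 replicate 4 (0.089 and 0.28). Type I interferon genes, among them the nucleic acid sensor Zbp1, had 0.14 (camera adjusted p = 0.043, and adjusted p = 0.96 with an estimated correlation). Zbp1 passed when adjusted over the list alone, which does not correct for the number of lists. The authors' deposited table of SW033291 gave it a mean level of 3.89 normalised counts and an unadjusted DESeq2 p of 0.11. The interferon call ended in 4 of the 6 fits that left out 1 library, with camera adjusted p from 0.085 without aged vehicle replicate 2 and 0.087 without aged vehicle replicate 3 to 0.094 without SW033291 replicate 4 and 0.50 without SW033291 replicate 1.

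The list of TGF-beta, myostatin and activin signalling, a pathway that restrains muscle growth and promotes matrix deposition, had 27 of 32 genes lower. Its relative median of -0.22 did not pass (camera adjusted p = 0.052, and adjusted p = 0.96 with an estimated correlation). It passed under median-of-ratios scaling, quantile normalization and rescaling without the 20 most abundant genes (camera adjusted p = 0.0055, 0.016 and 0.029) and with only the 2 groups compared (0.022), but in none of the 6 fits that left out 1 library (0.054 to 0.13) and not with the length and GC trend removed (0.37). Smad3, the transcription factor of the pathway, stood at 63.2 TPM with vehicle and 38.4 TPM with SW033291 (relative difference -0.57), and the ligands Tgfb2 and Tgfb3 had -0.48 and -0.28. None of these 3 genes passed over all genes or when adjusted over the list alone. The aged vehicle libraries of batch 2 held more Smad3 than those of batch 1. Its difference with SW033291 may thus rest in part on high vehicle values, which was not tested. IGF and insulin signalling genes had a relative median of -0.10 (camera adjusted p = 0.15). Of these, Igf2r and Igfbp5 passed when adjusted over the list alone, which does not correct for the number of lists.

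**Figure D3:**
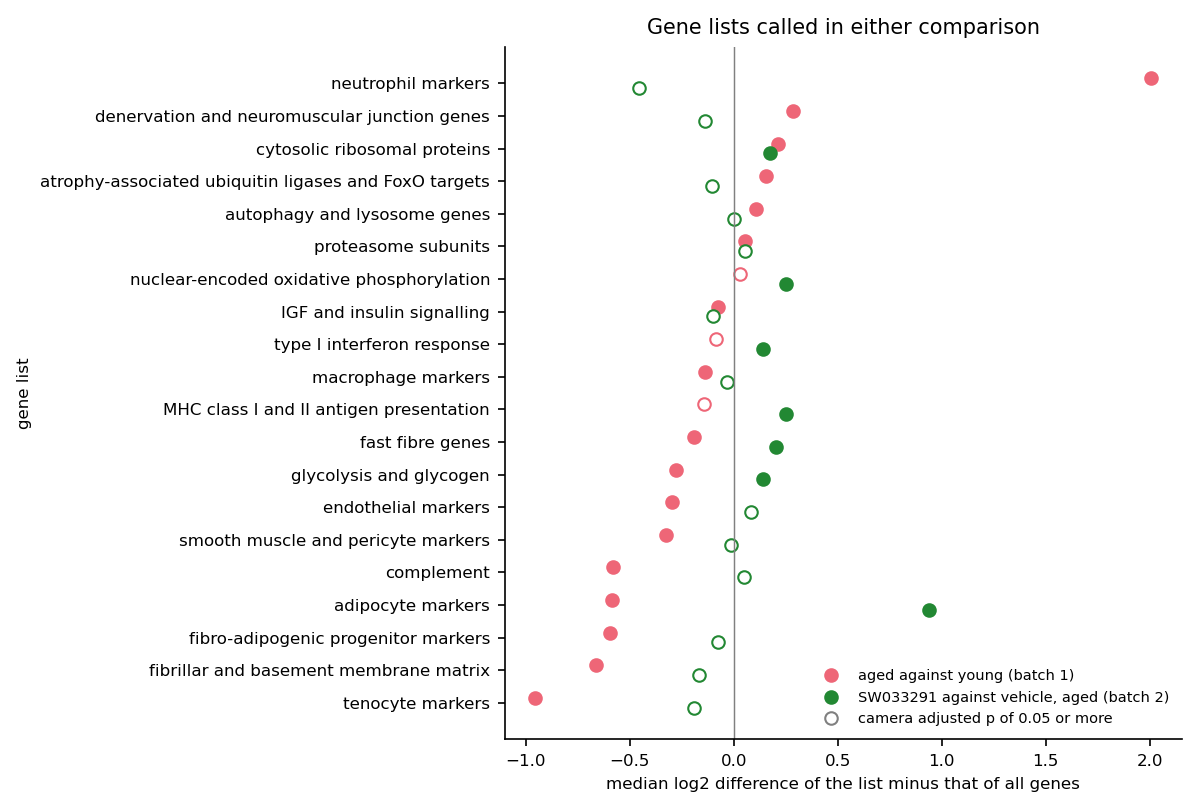
Median log2 difference of each gene list called in either comparison, minus that of all genes, on the horizontal axis; filled points passed camera with the preset correlation, and none passed with an estimated correlation. Matrix lists stood lower with age, at -0.66 for fibrillar and basement membrane matrix, and oxidative phosphorylation stood 0.25 higher with SW033291.

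The authors' deposited table of SW033291 against vehicle held p-values for 16666 genes, of which 456 (2.74%) were under 0.05, with 195 higher and 261 lower. That is a smaller share than the 0.05 that chance gives, and the median log2 change there was -5.6e-04. The excess of small p-values found with limma on TPM was thus not seen there. After Benjamini-Hochberg adjustment of the p-values in the authors' deposited table, 1 gene stayed under 0.05. It was Slc15a2, a peptide transporter, with a log2 change of 3.99 (adjusted p = 0.0039 from the authors' deposited table), named here after its value was seen. All other genes of the authors' deposited table had an adjusted p of 0.25 or more, among them Smad3, with a log2 change of -0.57.

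Whether SW033291 moves the genes that differ with age was asked of the calls above, in libraries that the age comparison in batch 1 does not use. Of the 44 genes higher with age 31 were lower with SW033291, with a median log2 difference of -0.17, against -0.13 for all genes, and under quantile normalization -0.16 for the 41 genes higher with age there, against -0.01 for all genes. That set was not called by fry either. Fry, adjusted over both directions, did not call this set (adjusted p = 0.11), and camera, which compares it with the other genes, gave an adjusted p = 0.90. Of the 10 genes lower with age, 4 of them in the fibrillar and basement membrane matrix list, 8 were also lower with SW033291, with a median of -0.23 (fry adjusted p = 0.21). The set higher with age passed fry without SW033291 replicate 1, with a median of -0.20 (fry adjusted p = 0.014), and in none of the other 5 fits that left out 1 library. Across the 11876 genes, which are not independent replicates, the log2 differences of both comparisons had Pearson's r = -0.14 and Spearman's rho = -0.11.

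The comparison of aged vehicle muscle between batches asks whether the batches differ with age and treatment held the same. With limma, 267 genes passed, 204 higher and 63 lower in batch 2, and 2148 had an unadjusted p under 0.05. With only the 2 groups compared in the fit, 1 gene passed, Aldoart1, a copy of the aldolase gene. The median log2 difference of all genes was 0.11, and -0.01 under median-of-ratios scaling. The direction depended on scaling, with 46 higher and 98 lower under median-of-ratios scaling and 53 and 45 under quantile normalization. The ribosomal protein list was lower in batch 2, with a relative median of -0.38 (camera adjusted p = 8.2e-31, and adjusted p = 0.67 with an estimated correlation), and 13 of its genes passed over all genes and 33 when adjusted over the list alone. The oxidative phosphorylation list was also lower, at -0.23 (camera adjusted p = 3.9e-15, and adjusted p = 0.67 with an estimated correlation). Of its genes 10 passed lower over all genes, and when adjusted over the list alone 23 passed lower and 2 higher. These are the 2 lists called between the batches, and both were higher with SW033291 within batch 2, a comparison that uses the same aged vehicle libraries of batch 2. The gene count was 18 without aged batch 1 replicate 2, 21 without aged batch 2 replicate 2, 21 without aged batch 2 replicate 3, 478 without aged batch 2 replicate 8 and 1643 without aged batch 1 replicate 4. Age could not be compared within batch 2, nor SW033291 within batch 1, since each batch lacks one of the groups.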

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

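The tests on adipocyte markers, on neutrophil and erythroid transcripts, on the trend on transcript length and GC and on how many aged libraries were high in ribosomal genes were chosen after the result was seen, as were the lists of B cell precursor and dividing cell genes, and the others in this part before.

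Among the 4 young libraries, 6 of 83 values tested had 1 library far from the other 3, by the gap to its nearest neighbour as a share of the whole range. Chance gives about 1 in 20 for independent values with normal spread, which these values need not have. The genes among them were those named in the text, so that part of the set followed from the results. Cox7a1 stood at 1551 TPM in replicate 5 against 1416 to 1432 TPM (share 0.880), and Psmb1 at 185.6 TPM in replicate 4 against 168.5 to 171 TPM (share 0.844). The median of the oxidative phosphorylation list was -0.05 in replicate 4 against 0.01 to 0.02 (share 0.834). Hba-a1, Gm14305 and Ltf were each listed at 0 in 3 young libraries and stood at 19.6 TPM in replicate 5, 0.09 TPM in replicate 3 and 0.04 TPM in replicate 5 (share 1 for each). With 3 values of 0 the share is 1 whatever the remaining value, so these 3 genes say little.

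Oxidative phosphorylation genes stood 0.25 above all genes with SW033291. In the 6 fits that left out 1 library this excess was 0.22 to 0.29, which argues against 1 deviating library as its whole source. The list's own median fell from 0.12 to 0.06 without SW033291 replicate 1. The largest camera adjusted p over these fits was 6.1e-11. They used the preset correlation of 0.01, while the estimate for this list was 0.19, so that p-value decides little. Genes of the same abundance, length and GC content shared part of the excess, since 10000 matched random lists had a median 0.14 above all genes. The highest of them lay 0.20 above all genes, and the list at their 100th percentile. Their genes were drawn independently, so these lists lack the shared movement of the real list and can spread too little. The percentile therefore does not decide whether these properties account for the whole excess. A trend of the libraries on transcript length and GC cannot be told apart from the rest: once it was removed the excess was 0.11 and the camera adjusted p = 0.0024, and removing it may also remove part of a real change in short genes. An effect of SW033291 on these genes stays open as a hypothesis, with an adjusted p = 0.23 under an estimated correlation and vehicle libraries of batch 2 that were low in this list.

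Adipocyte markers stood 0.94 above all genes with SW033291, and SW033291 replicate 1 held Cfd at 1267 TPM and Fabp4 at 1732 TPM against 118 and 552 TPM in replicate 4 and 157 and 501 TPM in replicate 6. A rise of that size in every treated animal is argued against, since only 1 of the 3 treated libraries lay above all 3 vehicle libraries in the list's median. It stood at 1.64 in SW033291 replicate 1, but at -0.44 and -0.57 in replicates 4 and 6. These medians were not taken relative to all genes, so a smaller rise in each treated library stays open. Adipose tissue in SW033291 replicate 1 is a candidate explanation, and without that library the median excess was 0.17. It stays open whether it accounts for all of the excess, because 15 of the 20 genes still stood above the median of all genes. Young replicate 1 was as high in this list (1.68, against 1.64 in SW033291 replicate 1), so high values were not limited to treated muscle.

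Neutrophil and erythroid transcripts were high in aged vehicle batch 1 replicate 4, aged vehicle batch 2 replicate 2 and, for neutrophils, SW033291 replicate 4. Bone marrow in these samples is a candidate explanation: in 3 of 3 libraries the mean TPM of granulocyte precursor genes (24.7, 12.7 and 3.83) and of erythroid precursor genes (3.73, 1.42 and 0.07) lay above the other 10, where the highest were 0.11 and 0.05, so the third erythroid value is a narrow one. Of 11 granulocyte precursor genes 5 are also in the neutrophil list, among them the most abundant, Camp (112, 32.3 and 8.82 TPM) and Ngp (99.7, 70.9 and 16.9 TPM). The other 6 had means of 4.30, 1.88 and 1.14 TPM against 0.17 TPM or less in the other 10 libraries. No sort would have removed such cells from whole muscle. The 3 libraries were picked by their neutrophil transcripts, so high granulocyte genes in them were likely beforehand. B cell precursor genes did not set them apart (0.88, 0.65 and 0.37 TPM, against up to 0.69 TPM in the other 10). Dividing cell genes did (2.12, 1.20 and 0.485 TPM, against up to 0.29 TPM). An effect of SW033291 as the source in all 3 libraries is argued against, since 2 of the 3 were given vehicle, and for SW033291 replicate 4 it stays open, since 1 of the 3 SW033291 libraries and 1 of the 3 vehicle libraries of batch 2 were high. Age stays open and untested as a source, since all 3 libraries were aged, and blood was not told apart from marrow for mature neutrophil transcripts such as S100a8 (684, 310 and 100 TPM).

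For ribosomal protein genes with age in batch 1, the excess over all genes was 0.21 before and 0.15 after the trend on length and GC was removed (camera adjusted p = 8.3e-13, and before removal adjusted p = 0.24 with an estimated correlation), and 4 of the 6 aged vehicle libraries of both batches lay above all young libraries.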

How the results depend on the processing

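The fits with length and GC trend removed, with aged vehicle of batch 2 in place of batch 1 and with the 3 libraries holding granulocyte precursor transcripts left out, and for gene lists also median-of-ratios scaling, leaving out the 20 most abundant genes and aged vehicle of both batches, were chosen after the result was seen, and the others before. Where a value changed, the cause was not tested unless given.

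For genes changed with age (54), an adjusted p under 0.1 gave 155, no filter 27 (more genes were tested), only the 2 groups compared 24, array weights 361, length and GC trend removed 146, aged vehicle of both batches 297 and aged vehicle of batch 2 in place of batch 1 1679, of which 47 were among the 54, with the same young libraries in both. Leaving out 1 library gave 19 to 92 genes. Pseudocounts of 0.1 and 5 (58 and 46), a filter at 5 TPM (70), the 3 scalings, robust fits and leaving out the 3 libraries (71, of which 30 were among the 54) stayed within 1.5 times. With aged vehicle of batch 2 in place of batch 1, the differences of Smad3 (0.59), Uqcrq (-0.35) and Myh4 (0.76) reversed, and none of the 3 had been called. Young libraries exist in batch 1 only, so fits that use aged vehicle of batch 2 mix age with batch. Each named gene was counted once in each alternative. Named genes called with age kept their direction and call in 394 of these cases and lost the call in 133. Those not called with age gained a call in the same direction in 154 cases, and those not called with SW033291 in 5. Without a call, they moved by at least their SE in 298 and 253 cases.

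For gene lists, an estimated correlation gave 0 with age and 0 with SW033291, and fry, which tests a list against no change and not against the other genes, 6 and 0. Other alternatives run for lists, among them leaving out 1 library (13 to 19 lists with age, 5 to 9 with SW033291), stayed within 1.5 times the 17 and 7.

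For SW033291 the count of 0 genes became 4 with a pseudocount of 0.1 (1700020L24Rik, Cdc42ep5, Gm16740 and Inca1) and 4 without the 3 libraries (Gm14305, Gm7367, Hbb-bs and Rab4b). Leaving out 1 library gave 0 to 1. The other alternatives gave 0 in limma.

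Between batches (267), median-of-ratios scaling gave 144, quantile normalization 98, only the 2 groups compared 1 (Aldoart1), array weights 1766, length and GC trend removed 163 and leaving out the 3 libraries 1037. Leaving out 1 library gave 18 to 1643.

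For genes higher with age, the median with SW033291 (-0.17) was -0.18 with a pseudocount of 0.1 and -0.31 over the genes of the authors' deposited age table, and both passed fry before adjustment. Judged by its correlation with the pooled TPM, that age table seems to share the aged vehicle libraries of batch 2. The median of genes higher with age was -0.30 for age calls with an absolute log2 change of at least 1 and -0.11 without the 3 libraries, and neither passed. For genes lower with age, the median (-0.23) was -0.48 for age calls with an absolute log2 change of at least 1, -0.11 under quantile normalization and -0.08 over the genes of the authors' deposited age table, and none of these passed. Leaving out 1 library gave -0.22 to -0.10 (without SW033291 replicate 4) for genes higher with age, and -0.29 to -0.02 (without SW033291 replicate 6) for genes lower with age.

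The replicate numbers that groups share showed no clear pairing of samples. Deviations of same-numbered libraries had correlations of 0.17 and 0.04 for age and -0.15 and -0.06 between batches, across genes. Those of libraries with different numbers ran from -0.26 to 0.28 for age and from -0.18 to 0.19 between batches. So few shared numbers cannot exclude pairing. A fit with a replicate block gave 6 genes with age (Eif3j1, Hba-a1, Mir6340, Rrad, Sln and Snora16a) and 905 between batches, from the few libraries that share a number. No paired analysis was possible for SW033291 because its groups share no number. Depth is unknown, so what depth limits could not be worked out.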

Other observations

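The lists of B cell precursor and dividing cell genes, the splits by unadjusted p with age, and the genes named from the comparison of batches, were chosen after the result was seen.

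Other splits of the same libraries into groups of the same sizes were counted. For genes changed with age, 1 of 35 splits of the batch 1 libraries, the real one, gave 54 genes and the highest other gave 0. That is the smallest share that 35 splits can give. It lies under 0.05, which argues against chance for this count alone. For the count at an unadjusted p under 0.05 with age, 2 of 35 splits gave as many as the real 1178, the highest other 1406, so chance cannot be excluded. For gene lists with age, 5 of 35 splits gave as many as the real 17, the highest other 21, so chance cannot be excluded. The 6 libraries of a comparison within batch 2 have 10 splits, too few for a share under 0.05. There, SW033291 gave 0 genes with limma against at most 2 in another split, 1221 genes at an unadjusted p under 0.05 against 1036, and 7 lists against 14. The size of the median change of genes higher with age was 0.17 against 0.12, and that of genes lower with age 0.23 against 0.35.

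Between the batches, the 10 splits of the 6 aged vehicle libraries are also too few for a share under 0.05. The real split called 267 genes and the highest other 1367. That split set aged batch 1 replicates 2 and 3 and aged batch 2 replicate 8 against the rest, which points to a structure of the samples other than batch. Both libraries with the most granulocyte precursor transcripts are on 1 side of it, and leaving out the 3 such libraries called 1037 genes between the batches. The remaining library on that side, aged batch 2 replicate 3, had a mean of 0 TPM of these transcripts, so they do not account for that split alone.

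Among genes that differed between the batches, Aldoart1, a copy of the aldolase gene whose reads can be shared with others, was 2.76 higher in batch 2 on the log2 scale, and Smad3 was 1.28 higher. Mean TPM of B cell precursor genes was 0.88 in aged vehicle batch 1 replicate 4 and 0.65 in aged vehicle batch 2 replicate 2, against up to 0.69 in the other libraries. It was 0.37 in SW033291 replicate 4. Dividing cell genes stood at 2.12 and 1.20 TPM in those 2 libraries and at 0.485 TPM in SW033291 replicate 4, against up to 0.29 TPM in the other 10.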
